A study of Mus musculus with 15 samples.

How the data were processed

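Gene expression was measured on 15 Affymetrix arrays of mouse NIH3T3 cells. Per the labels' protocols, the cultures were grown to confluence over 7 days and given ethanol (0.2%) alone or with 4-OHT for 24 h before RNA extraction, and biotin-labelled RNA was hybridised. The labels give a 4-OHT concentration of 0.1 mM, and they do not state for each constitutive line whether it had ethanol or 4-OHT. Samples were placed in 8 groups by their titles, which number them as biological replicates 1 and 2. Nothing says that they came from separate cultures or transductions, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. The deposited values are on a log2 scale. Per the labels' protocols, the authors read the arrays with GCOS and normalized them with the Robust Multichip Average (RMA) method of the Bioconductor module affy within the FunAlyse pipeline, and their versions and the probe-set definition file are not given in the sources used here. RMA subtracts background, forces the arrays to the same distribution and shrinks differences of dim probe sets, so that folds from or to the lower end are understated and stand for lower bounds and a change in total RNA would not be seen. The log2 scale was taken from the range of the values, and the 15 columns of the table were matched to samples by their accessions. No array was identical to another.

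Each array held 45101 probe sets, of which 34958 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and 64 were control probe sets of the manufacturer, some of which also carried a symbol. Symbols were compared with current ones through the Entrez identifier for 34754 probe sets, and none changed. For each of 18194 genes the probe set with the highest mean over all arrays was used. In 325 pairs of a named gene and a comparison the gene had other probe sets, and in 133 of these none of them was called the same way, while in 1 another was called the opposite way. The test was limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) with 1 coefficient per group over all 15 arrays, so that all groups shared the estimate of the spread (7 residual and 5.65 prior degrees of freedom). Two-sided p-values were adjusted by the Benjamini-Hochberg method over genes within each of the 12 comparisons, with a threshold of 0.05, and folds are 2 to the power of the log2 difference of group means. A group with 1 array, in the human RUNX1 line or when a replicate was left out, was assumed to vary like the others.

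The groups, the comparisons, the tests, 31 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for the average of the 3 mouse lines and for the induction beyond 4-OHT, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap, and for the average also past it with the same sign in each line, ranked by the smallest of the 3 changes. For other comparisons it took the 5 largest each way, and for each list up to 4 members past the threshold with the largest change, as well as the Runx genes. Probe sets without a symbol or of predicted or RIKEN clones were skipped in naming. Genes named in the closing part because they changed in opposite directions in 2 lines were chosen after their values were seen. Lists with at least 5 measured members were tested, 30 in number, with camera at its preset correlation of 0.01 between genes, with camera at a correlation estimated per list, and with fry, adjusted over lists within a comparison. The list of Runx genes and Cbfb had too few measured members for a test, and its genes are reported singly.

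For lines that share the vector arrays, correlation, overlap and agreement of sign were simulated 100 times for unchanged groups set against the same controls (for overlap and sign also with as many genes taken by p as were called in the data, since unchanged groups have almost no calls), computed for independent lists, and repeated with the vehicle and the 4-OHT vector arrays as separate controls. Correlations of fold changes were taken over the 8049 genes with a mean above 5 log2 units over all arrays and corrected for noise with the mean residual variance of those genes. The steps were tested on simulated data. For Runx1 against vector over 18194 genes, 32 of 67 genes changed by 0.5 log2 units were recovered (47.8%), 64 of 67 changed by 1 (95.5%) and 66 of 66 changed by 2, and 5 of 17994 unchanged genes were called. For Runx2 against vector, a list shifted by −0.5 was called and 0 of 29 others. The simulated genes varied independently of each other. The 0 of 29 therefore says nothing about false calls of lists whose genes vary together. For RUNX1-ER induction with Runx1, a true correlation of 0.6 over all 18194 genes, a wider set than that of the reported correlations, was returned as 0.595 with the correction and 0.428 without. The alternatives were an intensity trend with robust prior variance, array weights, quantile normalization again, centring on array medians, only genes with a group mean of at least 6, the mean of a gene's probe sets, all probe sets, a change of at least 1 log2 unit, only the groups compared, the replicate number as a block, other vector arrays as control, and each replicate left out in turn. For the gene lists, quantile normalization again, median centring and leaving out replicates were added after seeing the data. Scanner files were not used here.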

Results

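Expression was measured with Affymetrix arrays in NIH3T3 cells, an immortalised line of mouse fibroblasts, after retroviral transduction with the vector pBabe-puro, either empty or carrying a gene of the Runx family of DNA-binding transcription factors. The 15 arrays fell into 8 groups. The empty vector was profiled without and with 4-hydroxytamoxifen (4-OHT), and cells with RUNX1-ER, an inducible form of human RUNX1, were profiled uninduced and induced with 4-OHT, with 2 arrays in each of these 4 groups. Lines that expressed mouse Runx1, mouse Runx2 or mouse Runx3 constitutively gave 2 arrays each, and a line with human RUNX1 gave 1 array. Going by its title, the study asked which genes of cell adhesion and survival belong to a programme controlled by Runx proteins. The median of all 45101 probe sets lay between 3.69 and 3.75 log2 units on every array, and the SD over genes of the difference between replicates ran from 0.162 in vector cells to 0.220 in vector cells with 4-OHT. Not every array was closest to its own replicate. Replicate 1 of uninduced RUNX1-ER had its highest correlation across probe sets with vector replicate 1 (r = 0.996, against 0.994 with its own replicate), both vector arrays with 4-OHT had theirs with vector replicate 2, and Runx2 replicate 2 had its highest with an induced RUNX1-ER array.

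The inserted gene was visible on the arrays for mouse Runx1. In the Runx1 line the brightest Runx1 probe set read 9.21 ± 0.14 (log2, SD, n = 2) against 4.65 ± 0.13 in vector cells, a log2 difference of 4.55 (SE 0.12, limma adjusted p = 2.86e-10 over all probe sets), and another read 7.23 against 4.29. The gene Runx1 lies on chromosome 16 from 92601466 to 92826074 (GRCm38.p6). The brightest Runx1 probe set read 4.69 in the line with human RUNX1, which carries the gene of another species. A further Runx1 probe set was lower in the Runx1 line by a log2 change of −0.68 (adjusted p = 0.0238), in the Runx3 line by −0.95 (adjusted p = 0.000485) and after induction of RUNX1-ER by −0.79 (adjusted p = 0.00854). It changed by −0.27 in the Runx2 line (limma adjusted p = 0.525) and by −0.73 on the single array with human RUNX1. With 4-OHT in vector cells it changed by −0.33. Set against that, the induction value was −0.46 (limma adjusted p = 0.507) and did not pass. The other Runx1 probe sets changed by −0.43 to 0.17 on induction, and none passed. The brighter of the Runx3 probe sets differed by −0.24 between the Runx3 line and vector cells (adjusted p = 0.557), and because its place relative to the inserted sequence is not known here, it checks nothing. No probe set carried the name Runx2 in the annotation used. A probe set of Esr1, the oestrogen receptor alpha gene, read 6.51 ± 0.72 in uninduced RUNX1-ER cells against 4.06 ± 0.28 in vector cells. This rise of 2.45 (SE 0.25, limma adjusted p = 0.00272) missed the threshold without vector replicate 1. The other Esr1 probe sets changed by 0.09 and −0.10 and did not pass. Cbfb, the gene of the DNA-binding partner of Runx proteins, read 9.46 in vector cells and passed the test in none of the 12 comparisons, with a log2 change of 0.09 in the Runx3 line (adjusted p = 0.649).

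Which genes did Runx1, Runx2 and Runx3 change alike? Rdh10, an enzyme that oxidises retinol on the way to retinoic acid, rose 5.26-fold in the Runx1 line, 7.86-fold in the Runx2 line and 6.72-fold in the Runx3 line (SE 0.11 on the log2 scale, n = 2 arrays per group). Emilin1 and Mfap5, glycoproteins of elastic fibres and microfibrils, rose by 1.66, 2.14 and 3.19 and by 1.57, 1.51 and 2.29 log2 units in the same order (the other probe set of Mfap5 changed by 0.35, 0.12 and 0.93, and passed only in the Runx3 line), and Ugcg, which makes glucosylceramide, rose by 1.41, 2.29 and 2.62. The chemokine genes Ccl2 (1.15, 1.00 and 1.92) and Ccl7 (1.55, 1.23 and 1.72) also rose. Id2 and Id3, inhibitors of basic helix-loop-helix transcription factors, fell, Id2 by log2 changes of −1.68, −2.25 and −2.71 and Id3 by −1.22, −1.50 and −1.40. Vip, a neuropeptide gene, Ptgfr, a prostaglandin receptor, and Rgs2, a regulator of G protein signalling, had average changes over the 3 lines of −2.00 (SE 0.13, adjusted p = 1.76e-06), −2.01 (SE 0.11, adjusted p = 2.84e-07) and −1.94 (SE 0.10, adjusted p = 2.18e-07). The size for Vip depended on the control, with an average of −1.15 (adjusted p = 0.000157) against the vector arrays with 4-OHT, where that of Rdh10 was 3.38 in place of 2.71.

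**Figure D1:**
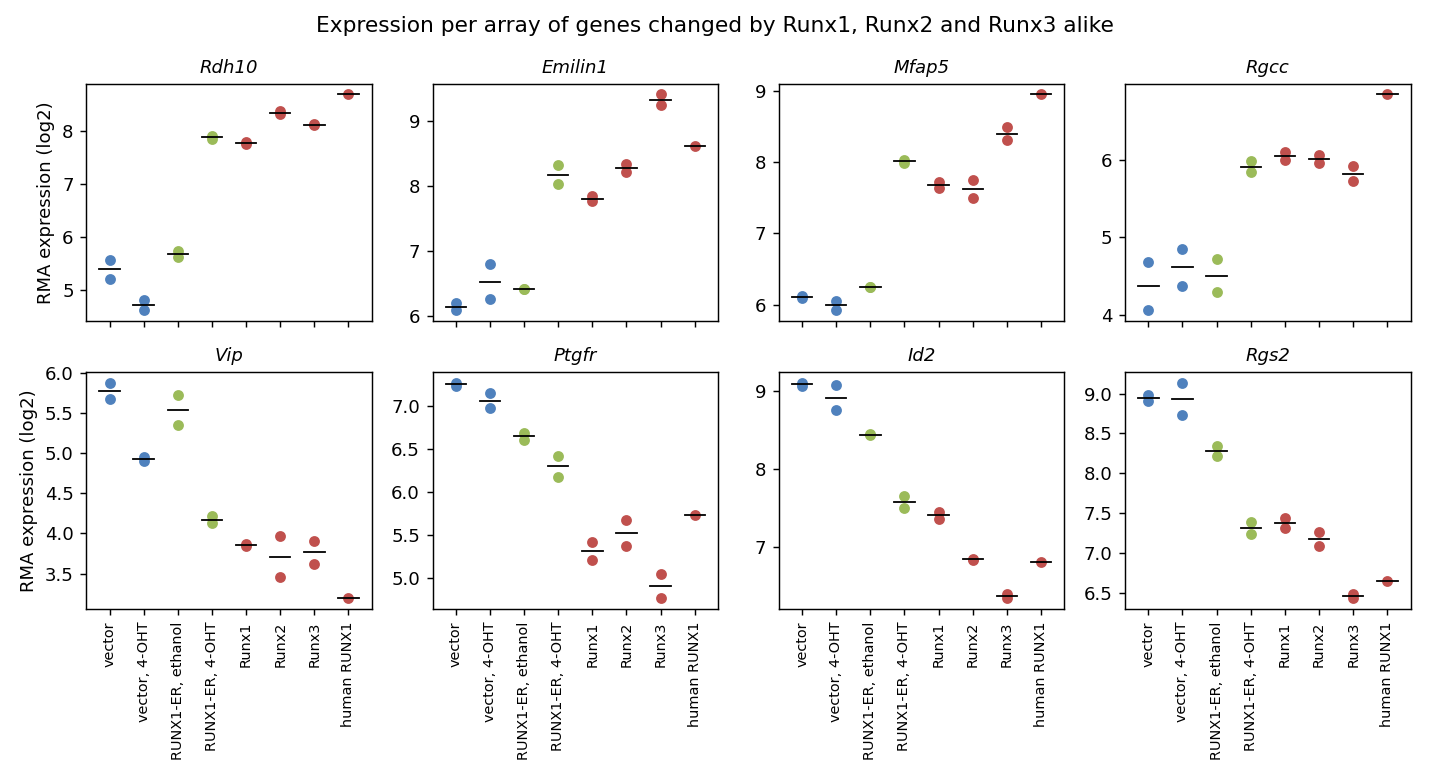
RMA expression (log2, vertical axis) of Rdh10, Emilin1, Mfap5, Rgcc, Vip, Ptgfr, Id2 and Rgs2 on each array of the 8 groups (horizontal axis), with points for arrays and a line for each group mean. Rdh10 had a mean of 5.38 in vector cells and of 7.78, 8.36 and 8.13 in the Runx1, Runx2 and Runx3 lines, and Id2 a mean of 9.09 in vector cells and of 6.38 in the Runx3 line.

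In limma 148 genes passed the threshold with the same sign in all 3 lines, 61 of them higher and 87 lower (119 and 96 against the vector arrays with 4-OHT). Independent lists of the same lengths would share 0.0649 higher and 0.117 lower genes, and simulated unchanged groups set against the same vector arrays shared 0 calls on average over 100 draws, having almost none to share, but 39.6 genes when as many were taken by p as were called here. The vehicle and the 4-OHT vector arrays were then divided among the lines in 6 assignments, in each of which 2 of the 3 lines still shared a control. Between 145 and 190 genes passed, with at least 126 of the 148 among them each time. The average over the 3 lines changed 860 genes, 342 higher and 518 lower (753 and 532 against the vector arrays with 4-OHT), and Runx1 itself is among them through its transgene. The 148 became 69 without vector replicate 1, 69 without vector replicate 2, 96 without Runx1 replicate 1 and 86 without Runx1 replicate 2, and the 860 became 371 without vector replicate 1 and 377 without vector replicate 2.

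**Figure D2:**
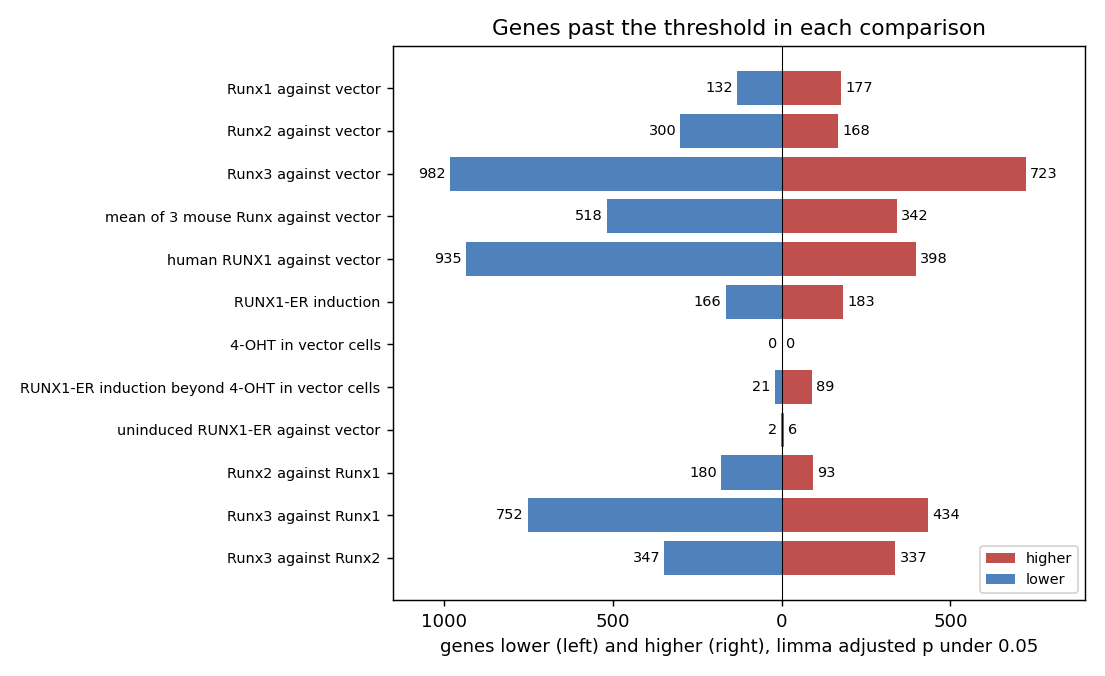
Number of genes lower (bars to the left) and higher (bars to the right) at a limma adjusted p under 0.05 in each of the 12 comparisons. The Runx3 line changed 1705 genes, the Runx2 line 468 and the Runx1 line 309, and 4-OHT in vector cells changed 0, with 1225 genes at an unadjusted p under 0.05.

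Pairs of lines shared calls, part of which the common vector arrays would give without any effect. The Runx1 and Runx2 lines shared 164 calls of the same sign (70 higher, 94 lower), where independent lists would share 1.63 and 2.18. The Runx1 and Runx3 lines shared 211 (102 and 109, against 7.03 and 7.12), and the Runx2 and Runx3 lines 391 (129 and 262, against 6.68 and 16.2). Simulated unchanged groups with the same controls shared 0 calls, but 63.5, 128 and 178 genes of the same sign when as many were taken by p as were called here, and their log2 changes correlated at 0.50, 0.501 and 0.503 across the 8049 brighter genes, where the lines correlated at 0.615, 0.544 and 0.771. The observed covariances of 0.0374, 0.0503 and 0.0782 stood beside simulated ones of 0.00717, 0.00718 and 0.00720. With the vehicle and the 4-OHT vector arrays split between the lines, the shared calls were 164 and 173 for Runx1 with Runx2, 209 and 266 for Runx1 with Runx3, and 367 and 416 for Runx2 with Runx3, and the correlations were 0.530 and 0.495 for Runx1 with Runx2, 0.483 and 0.491 for Runx1 with Runx3, and 0.692 and 0.724 for Runx2 with Runx3. Genes are not independent replicates, so these correlations carry no p.

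The comparison of the Runx1 line with vector cells asked which genes stable Runx1 changed. Cp, which encodes the ferroxidase ceruloplasmin, rose 5.45-fold, from 4.02 ± 0.17 to 6.47 ± 0.14 (log2, SD, n = 2; adjusted p = 6.24e-06). Casp4 and Casp12, caspases of the inflammatory group, rose by 1.51 (SE 0.19) and 1.15 (SE 0.14) log2 units, and Tgfbr2, a TGF-β receptor, rose by 1.16 (SE 0.10, adjusted p = 5.57e-05). Chac1, which degrades glutathione, rose by 1.84 (SE 0.23, adjusted p = 0.000869), as did Cth, an enzyme of cysteine synthesis, by 1.49 and Trib3, a stress-induced pseudokinase, by 1.03 (adjusted p = 0.00274, or 0.0627 as the mean of its probe sets). The largest falls by the rule for named genes included Ptgfr at −1.95 and Vip at −1.92 (−1.07 against the vector arrays with 4-OHT). In all, 177 genes were higher and 132 lower, of which 50 and 21 changed at least 2-fold, and 1770 genes had an unadjusted p under 0.05. The total of 309 became 143 without vector replicate 1, 143 without vector replicate 2, 176 without Runx1 replicate 1 and 158 without Runx1 replicate 2.

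The same question was asked of Runx2. Of the 5 largest rises and 5 largest falls by the rule for named genes, it shared Rdh10, Id2, Vip and Rgs2 with Runx1. Hp, the gene of the haemoglobin-binding plasma protein haptoglobin, rose by 3.91 log2 units in the Runx2 line, from 3.91 ± 0.16 to 7.82 ± 0.13 (SD, n = 2; adjusted p = 6.73e-07). Akr1c14, an aldo-keto reductase of steroid metabolism, rose 11.9-fold, and Ifitm1, an interferon-induced membrane protein, rose 9.84-fold (adjusted p = 1.43e-06 and 1.32e-06). Tnc, the matrix protein tenascin C, rose by 1.78 (SE 0.13, and −0.05 on its other probe set) and Ccn5, a secreted matricellular protein, by 2.06 (SE 0.22). Car9, a carbonic anhydrase induced by low oxygen, fell from 6.52 ± 0.05 to 4.88 ± 0.16 (adjusted p = 0.000840), and Cebpd, a transcription factor gene, had a log2 change of −1.73 (SE 0.12, and −0.54 on its other probe set, which did not pass). Of 468 genes past the threshold 168 were higher and 300 lower, with 35 and 50 changed at least 2-fold, and 2279 had an unadjusted p under 0.05. This total became 207 without vector replicate 1, 224 without vector replicate 2 and 270 without Runx2 replicate 1.

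The Runx3 line differed from vector cells in the most genes of the 3 mouse lines. Ifitm1 rose by 4.39 log2 units (SE 0.20), Anxa8, an annexin, 13.7-fold, Timp4, an inhibitor of matrix metalloproteinases, 11.6-fold and Ccr7, a chemokine receptor, 10.3-fold (adjusted p = 2.78e-08, 3.92e-08, 2.69e-08 and 1.29e-08, n = 2 per group). Snai1, a transcription factor that represses E-cadherin in epithelial-mesenchymal transition, rose by 2.43 (SE 0.20), and Cdh1, E-cadherin itself, was higher by at least 1.35 (adjusted p = 5.13e-05), at 4.22 against 2.87 in vector cells, a value under the 25th percentile of their arrays. Ackr3, an atypical chemokine receptor, fell from 9.30 ± 0.04 to 6.45 ± 0.05, and Pde8b, a phosphodiesterase of cyclic AMP, had a log2 change of −2.66 (SE 0.13). Cd34, a surface sialomucin of fibroblasts and progenitor cells, changed by −1.91 (SE 0.10) and Errfi1, a feedback inhibitor of EGF receptors, by −2.06 (SE 0.18). There were 723 higher and 982 lower genes, 107 and 147 of them by at least 2-fold, and 3579 with an unadjusted p under 0.05. Against the vector arrays with 4-OHT, more genes were higher (1173) than lower (876). The total of 1705 became 936 without vector replicate 1, 970 without vector replicate 2 and 1033 without Runx3 replicate 2.

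Differences between the family members were tested directly, line against line. Hp was higher in the Runx2 line than in the Runx1 line by 3.72 (SE 0.22, adjusted p = 1.82e-06), and lower in the Runx3 line than in the Runx2 line by a log2 change of −3.27 (adjusted p = 6.92e-06). Cp was lower in both other lines than in the Runx1 line, at −2.30 for Runx2 (adjusted p = 1.90e-05) and −2.40 for Runx3 (adjusted p = 3.75e-06). Timp4 exceeded its level in the Runx1 line by 2.97 and in the Runx2 line by 3.01 when Runx3 was expressed, and Ccr7 did so by 3.35 and 2.53. Trib3 differed in every pair, by −1.09 for Runx2 against Runx1, −2.13 for Runx3 against Runx1 and −1.04 for Runx3 against Runx2 (adjusted p = 0.00309, 3.35e-06 and 0.00206). The average of a gene's probe sets gave an adjusted p of 0.0516 for the last of these. Car9 was lower by −1.59 in the Runx2 line (adjusted p = 0.00257) and by −2.46 in the Runx3 line (adjusted p = 1.71e-05) than in the Runx1 line.

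Runx2 against Runx1 gave 273 genes (93 higher, 180 lower), Runx3 against Runx1 1186 (434 and 752) and Runx3 against Runx2 684 (337 and 347). For Runx2 against Runx1 the total was 94 without Runx1 replicate 1, 88 without Runx1 replicate 2 and 120 without Runx2 replicate 1. For Runx3 against Runx1 it was 672 without Runx1 replicate 1, 679 without Runx1 replicate 2 and 641 without Runx3 replicate 2, and for Runx3 against Runx2 it was 305 and 448 without Runx2 replicates 1 and 2 and 332 and 251 without Runx3 replicates 1 and 2.

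Among gene groups, many genes of hypoxia and glycolysis were lower in the Runx2 and Runx3 lines. Of 27 measured members, 1 rose, 13 fell and 13 were not called in the Runx2 line, with a median log2 change of −0.46, and 1 rose, 17 fell and 9 were not called in the Runx3 line, with a median of −0.49. The member that rose was Vegfa in the Runx2 line, by 0.66, and Ddit4 in the Runx3 line, by 0.62. Vegfa changed by 0.08 in the Runx3 line. Adjusted over the list alone, 1 rose and 20 fell in each line. Slc2a1, the glucose transporter GLUT1, changed by −1.21 and −1.45 in the 2 lines, Bnip3, a mitochondrial protein induced by low oxygen, by −0.97 and −1.17, and Egln1, an oxygen sensor that marks HIF proteins for degradation, by −0.98 and −1.03 (SE 0.11, 0.13 and 0.10). Camera, which asks whether a list moves further than other genes, gave adjusted p = 2.45e-18 for Runx2 and 4.45e-14 for Runx3 (adjusted p = 0.163 and 0.127 with an estimated correlation). In the Runx1 line 2 members rose, Vegfa by 0.73 and Ddit4 by 0.64, and 3 fell, with a median of −0.06 (camera adjusted p = 0.0548). The 3 were Egln3, a relative of Egln1, at −1.41, Mxi1 at −0.52 and Slc2a1 at −0.51, and the last 2 missed the threshold without vector replicate 1 (adjusted p = 0.120 for each), vector replicate 2 (0.255 and 0.291), Runx1 replicate 1 (0.152 and 0.103) or Runx1 replicate 2 (0.183 and 0.276). Tested directly, the list was lower in the Runx2 than in the Runx1 line (median −0.35, adjusted p = 1.01e-15, or adjusted p = 0.153 with an estimated correlation) and lower in the Runx3 than in the Runx1 line (median −0.46, adjusted p = 1.11e-13, or adjusted p = 0.0856 with an estimated correlation).

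Genes of cholesterol synthesis fell in the Runx3 line. Of 25 measured members, 1 rose, 16 fell and 8 were not called (2 and 19 adjusted over the list alone), with a median log2 change of −0.50. Pmvk of the mevalonate pathway fell from 7.00 to 6.06 (log2 change −0.94, SE 0.10, adjusted p = 2.93e-05), and Msmo1 and Nsdhl, which remove methyl groups from sterols, changed by −0.89 (SE 0.10, and −0.05 on the other probe set of Msmo1) and −0.80 (SE 0.09). Camera gave adjusted p = 2.02e-12, and adjusted p = 0.0254 with an estimated correlation. The list was also lower in the Runx3 line than in the Runx1 line (18 lower, median −0.62) and than in the Runx2 line (15 lower, median −0.51), with adjusted p = 0.00447 and 0.00533 with an estimated correlation. These 3 calls and that of the uninduced RUNX1-ER cells were the only 4 of 63 list calls that held with an estimated correlation. In the Runx1 line camera gave adjusted p = 0.000444 for a median of 0.15, or adjusted p = 0.181 with an estimated correlation.

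Some genes of the unfolded protein and amino acid stress responses rose in the Runx1 line, and some fell in the Runx3 line. In the Runx1 line 6 of 26 members rose and 20 were not called (10 rose and 1 fell adjusted over the list alone), led by Chac1 and Trib3. Camera called the list up (adjusted p = 0.00249, or adjusted p = 0.587 with an estimated correlation) although its median was −0.01, with a mean of 0.24. In the Runx3 line 1 rose, 7 fell and 18 were not called (1 and 11 adjusted over the list alone), with a median of −0.21 and adjusted p = 4.37e-05, or adjusted p = 0.304 with an estimated correlation. Trib3 changed by −1.10 (SE 0.15, adjusted p = 0.000433) in that line. Runx3 against Runx1, tested directly, had 10 members lower and a median of −0.29 (adjusted p = 1.92e-10, or adjusted p = 0.0856 with an estimated correlation).

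Some genes of ERK and G protein feedback and some immediate early genes were lower in the Runx2 and Runx3 lines. Of 30 feedback genes, 1 rose, 12 fell and 17 were not called in the Runx3 line (1 and 14 adjusted over the list alone), and 5 fell in the Runx2 line (7 adjusted over the list alone). Dusp1, a phosphatase of MAP kinases, changed by −0.86 in the Runx2 line and −1.46 in the Runx3 line (SE 0.12), and Rgs2 by −1.77 and −2.49. In the Runx1 line 1 rose, Dusp4 of the same phosphatase family by 0.98, and 2 fell, Rgs2 by a log2 change of −1.57 and Errfi1 by −0.92, the last of which missed the threshold without vector replicate 1 (adjusted p = 0.243), Runx1 replicate 1 (0.115) or Runx1 replicate 2 (0.157). Camera gave adjusted p = 1.74e-06 for Runx3 and 0.000700 for Runx2 (adjusted p = 0.0606 and 0.163 with an estimated correlation). Of 23 immediate early genes, 2 rose and 9 fell in the Runx3 line (4 and 10 adjusted over the list alone) and 4 fell in the Runx2 line (3 rose and 10 fell adjusted over the list alone). Jun, a subunit of the AP-1 transcription factor, changed by −1.12 and −1.59 (SE 0.17) in the Runx2 and Runx3 lines, while its relative Junb rose by 1.61 (SE 0.19) in the Runx3 line. The immediate early list had adjusted p = 0.00171 for Runx2 (0.0697 without vector replicate 1) and 0.00480 for Runx3 (0.0673 without vector replicate 1), or adjusted p = 0.568 and 0.635 with an estimated correlation.

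Some cell cycle genes were lower in the Runx3 line. Of 48 genes of S phase and mitosis, 9 fell and 39 were not called (13 fell adjusted over the list alone), with a median log2 change of −0.16 (adjusted p = 4.37e-05, or adjusted p = 0.143 with an estimated correlation). Nusap1, a spindle protein, changed by −0.69 (SE 0.11, adjusted p = 0.00109, and −0.12 on its other probe set) and Aurkb, a mitotic kinase, by −0.58 (SE 0.10, adjusted p = 0.00171). The list of p53 targets and CDK inhibitors had 2 of 24 members higher and 6 lower in the Runx3 line (adjusted p = 0.413), and was called lower in the Runx3 than in the Runx1 line (adjusted p = 0.0133, or adjusted p = 0.261 with an estimated correlation), a call that ended without Runx3 replicate 1 (adjusted p = 0.0534).

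**Figure D3:**
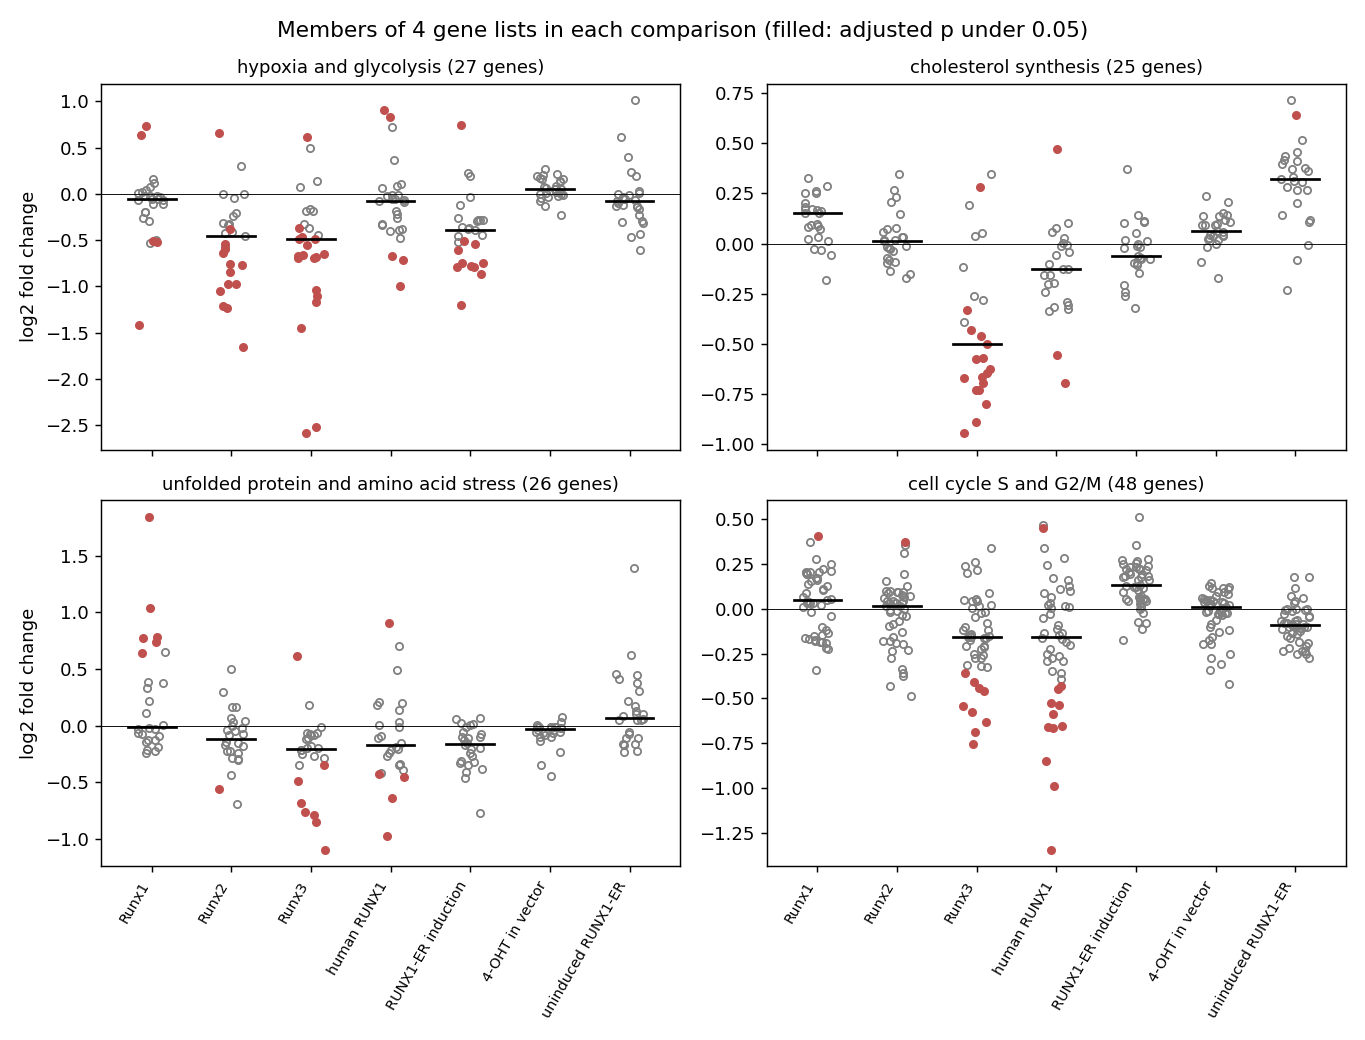
Log2 fold change (vertical axis) of each member of the lists for hypoxia and glycolysis (27 genes), cholesterol synthesis (25), unfolded protein and amino acid stress (26) and cell cycle (48) in 7 comparisons (horizontal axis). Filled points passed the adjusted p threshold and lines mark medians, such as −0.46 and −0.49 for hypoxia and glycolysis in the Runx2 and Runx3 lines and −0.50 for cholesterol synthesis in the Runx3 line.

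Some contractile genes and targets of SRF or YAP rose in the Runx1 line. Of 25 members, 6 rose and 19 were not called (10 rose adjusted over the list alone), with a median of 0.23 (adjusted p = 5.95e-10, or adjusted p = 0.0823 with an estimated correlation). Ccn2, a matricellular protein and YAP target, rose by 1.07 (SE 0.13, adjusted p = 0.000818) there and by 1.19 in the Runx3 line, where 6 members rose and 4 fell (adjusted p = 0.0849). Of 41 interferon response genes, 6 rose in the Runx1 line (9 adjusted over the list alone), among them the exonuclease gene Isg20 by 0.67 (SE 0.10, adjusted p = 0.00289), with a list median of 0.09 (adjusted p = 0.000184, or adjusted p = 0.219 with an estimated correlation). In the Runx2 line 3 rose and 1 fell (adjusted p = 0.00921, or adjusted p = 0.415 with an estimated correlation), a call that ended without vector replicate 2 (adjusted p = 0.164) or Runx2 replicate 2 (adjusted p = 0.137).

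The genes of cell adhesion, which the title of the series names, changed in both directions. Of 46 cell adhesion molecules, 4 rose, 12 fell and 30 were not called in the Runx3 line (4 and 12 adjusted over the list alone), 2 rose and 4 fell in the Runx2 line (3 and 10), and 3 rose and 1 fell in the Runx1 line (3 and 2). Ncam1, the neural cell adhesion molecule, rose by 0.95, 1.25 and 1.78 (SE 0.14) in the Runx1, Runx2 and Runx3 lines. Sdc1, the proteoglycan syndecan 1, rose in the same lines by 0.44, 0.87 and 1.40 (SE 0.09). Alcam, an adhesion molecule of activated leukocytes, changed by −0.73, −0.89 and −1.32 in the 3 lines. Pcdh18, a protocadherin, changed by −0.76 and −1.17 in the Runx2 and Runx3 lines. Among 19 integrin genes, Itgb5 rose by 0.71, 0.84 and 1.41 (SE 0.12) in the Runx1, Runx2 and Runx3 lines. Itga6 changed by −1.07 and −1.54 (SE 0.16) in the Runx2 and Runx3 lines. Itgb5 and Itga6 were the only calls among integrins in the Runx2 line. In the Runx3 line Itga3 rose by 0.42 and Itgb8 changed by −0.72 as well. Neither of these passed against the vector arrays with 4-OHT (limma adjusted p = 0.161 and 0.187). Camera called the adhesion molecules in the Runx2 line alone among the 3 lines (median −0.09, adjusted p = 0.0424, or adjusted p = 0.163 with an estimated correlation), and not without vector replicate 2 (adjusted p = 0.164) or Runx2 replicate 2 (adjusted p = 0.211). It gave adjusted p = 0.123 in the Runx3 line, where fry, which asks only whether a list moves one way on balance, gave adjusted p = 0.000180, and integrins reached 0.408 at the lowest over the 12 comparisons.

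Matrix genes were split as well. Of 47 extracellular matrix genes, 10 rose, 13 fell and 24 were not called in the Runx3 line, 4 rose and 7 fell in the Runx2 line and 1 rose and 5 fell in the Runx1 line (10 and 13, 10 and 10, and 3 and 11 adjusted over the list alone). Col5a1, a chain of collagen V, rose from 9.24 ± 0.12 to 11.53 ± 0.15 in the Runx3 line and by 0.90 in the Runx2 line, against a change of 0.00 in the Runx1 line (adjusted p = 0.996). Col6a2, of collagen VI, rose by 0.46 and 1.09 (SE 0.10) in the Runx2 and Runx3 lines. Fbln5, which assembles elastic fibres, changed by −0.67, −1.12 and −1.98 (SE 0.10) in the Runx1, Runx2 and Runx3 lines. The other Fbln5 probe set changed by −0.06, 0.06 and −0.06. Camera called the list lower in the Runx1 line only among the 3 (adjusted p = 0.0117, or adjusted p = 0.620 with an estimated correlation), and not without Runx1 replicate 1 (adjusted p = 0.179).

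Genes of apoptosis and survival changed singly. Of 41 members, 2 rose in the Runx1 line (Casp4 and Casp12), 3 rose and 2 fell in the Runx2 line and 2 rose, 7 fell and 32 were not called in the Runx3 line, where 4 rose and 7 fell adjusted over the list alone. Bcl2, which blocks mitochondrial apoptosis, rose by 1.21 (SE 0.14, adjusted p = 7.21e-05) in the Runx3 line, where its 4 other probe sets ran from −0.10 to 0.28 and none passed, and Tnfrsf1b, a receptor of tumour necrosis factor, changed by −0.98 (−0.31 on its other probe set, which did not pass). The lowest adjusted p of the list in camera was 0.112 over the 12 comparisons.

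Sphingolipid genes had been put on a list because some members have been described as Runx targets in these cells, so their counts are not independent evidence. Of 37 members, 2 rose and 1 fell in the Runx1 line, 3 rose and 1 fell in the Runx2 line and 4 rose, 8 fell and 25 were not called in the Runx3 line (4 and 1, 3 and 3, and 6 and 9 adjusted over the list alone). Next to Ugcg, St3gal5, the synthase of the ganglioside GM3, rose by 0.48, 0.69 and 1.13 (SE 0.09) in the Runx1, Runx2 and Runx3 lines. Sgpp1, a phosphatase of sphingosine 1-phosphate, changed in the same lines by −0.73, −0.95 and −1.59 (SE 0.10). Camera gave adjusted p = 0.0703, 0.820 and 0.854.

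Lists for other lineages and pathways were called rarely. In the Runx2 line camera called 8 of 30 lists, 1 higher and 7 lower, not all of which are described here. None of these held with an estimated correlation. The haematopoietic list was called lower in the Runx1 line, where 1 of 38 fell (median −0.10, adjusted p = 0.0184, or adjusted p = 0.172 with an estimated correlation), and not without vector replicate 2 (adjusted p = 0.131) or Runx1 replicate 1 (adjusted p = 0.105). In the Runx2 line, TGF-β and BMP genes (1 of 37 rose, 4 fell) and oestrogen response genes (1 of 13 fell) had adjusted p = 0.0424 and 0.0439, or adjusted p = 0.360 and 0.241 with an estimated correlation. The TGF-β and BMP call ended without vector replicate 1 (adjusted p = 0.0697), vector replicate 2 (0.0584), Runx2 replicate 1 (0.122) or Runx2 replicate 2 (0.0649), and the oestrogen response call without vector replicate 1 (0.0603), vector replicate 2 (0.164) or Runx2 replicate 1 (0.240). The lowest camera adjusted p over the 12 comparisons was 0.0837 for Wnt and Notch genes, 0.0975 for epithelial genes, 0.150 for housekeeping genes and 0.157 for osteoblast and chondrocyte genes. It was 0.211 for semaphorin, ephrin and slit guidance genes, 0.236 for inflammatory cytokines, 0.265 for matrix proteases, 0.287 for endothelial genes and 0.356 for oxidative and xenobiotic response genes. Neural genes, muscle genes and the IGF axis reached 0.425, 0.447 and 0.507.

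The line with human RUNX1 was represented by 1 array, so its values have no replicate check of their own, and limma took their spread from the other groups. Ifitm1 was 63.9-fold above vector cells, Rdh10 9.99-fold, and Tnc and Cyp1b1, a cytochrome P450 of oestrogen and retinoid metabolism, by 3.20 and 3.02 log2 units. Cp, which had risen in the Runx1 line, was higher by 2.65 (SE 0.21), and Vip and Rgs2 were lower by log2 changes of −2.58 (−1.73 against the vector arrays with 4-OHT) and −2.30. Of the 309 genes called in the mouse Runx1 line, 297 (96.1%) had the same sign here, as did 446 of the 468 of Runx2 (95.3%) and 1425 of the 1705 of Runx3 (83.6%). These comparisons share the vector arrays, and simulated unchanged groups gave 86.4%, 85.5% and 81.1% for as many genes taken by p. With the human array set against the 4-OHT vector arrays instead, 297 (96.1%), 436 (93.2%) and 1406 (82.5%) had the same sign. For mouse Runx1 the correlation was 0.614 across genes, against 0.411 for simulated unchanged groups, with covariances of 0.0516 and 0.00721. With split controls the correlation was 0.577 or 0.463. In all 398 genes were called higher and 935 lower, 1333 together, which became 524 without vector replicate 1 and 781 without vector replicate 2. When the deposited values were quantile normalized again the split was 566 higher and 484 lower. The contractile list was called higher (5 of 25 rose, adjusted p = 0.00410, or adjusted p = 0.557 with an estimated correlation), and the feedback list lower (1 of 30 rose and 8 fell, adjusted p = 0.0130, or adjusted p = 0.557 with an estimated correlation). Of 27 hypoxia and glycolysis genes 2 rose and 3 fell, with a median of −0.07 (adjusted p = 0.678).

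The vector cells with 4-OHT served as the control for the ligand. No gene passed limma's adjusted threshold, while 1225 genes had an unadjusted p under 0.05, and 4 genes passed without replicate 1 of the vector cells with 4-OHT. Rdh10 differed by −0.67 and Vip by −0.85 (SE 0.11 and 0.16), both with adjusted p = 0.298. Camera called 3 lists with small medians, cholesterol synthesis (0.06, adjusted p = 0.00198), hypoxia and glycolysis (0.05, adjusted p = 0.0196) and adipocyte genes (0.08, adjusted p = 0.0196), or adjusted p = 0.299, 0.983 and 0.299 with an estimated correlation. Each of these calls ended when single arrays were left out. For cholesterol these were vector replicate 2 (adjusted p = 0.0615) and 4-OHT replicate 1 (0.143), and for hypoxia vector replicate 1 (0.787) and 4-OHT replicate 2 (0.854). Adipocyte genes lost the call without any of the 4 arrays (0.0755 and 0.0709 without vector replicates 1 and 2, 0.143 and 0.188 without 4-OHT replicates 1 and 2).

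Uninduced RUNX1-ER cells were compared with vector cells to see what the fusion changed without ligand. Besides Esr1, 7 genes passed: Id1 changed by −1.18 (SE 0.12, adjusted p = 0.00272) and Phex, an endopeptidase of bone, by −1.23, while Clba1, Vash2, Fnip2, Fam110b and Mvd rose by 0.83, 0.80, 0.79, 0.68 and 0.64. Against the vector arrays with 4-OHT, Phex and Mvd did not pass (adjusted p = 0.123 and 0.0988). Genes of cholesterol synthesis, Mvd among them, were higher as a list, with a median of 0.32 over 25 members, 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.05e-21, and adjusted p = 0.00444 with an estimated correlation). Camera called 6 of 30 lists in this comparison, 3 higher and 3 lower. Only that of cholesterol synthesis also held with an estimated correlation. The total of 8 genes became 4 and 1 without RUNX1-ER uninduced replicates 1 and 2, and 0 and 3 without vector replicates 1 and 2, with 1447 genes at an unadjusted p under 0.05 on all arrays.

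Induction of RUNX1-ER for 24 h asked what RUNX1 activity changed within 1 line. Akr1c14 rose 7.57-fold, from 4.41 ± 0.08 to 7.33 ± 0.16 (log2, SD, n = 2; adjusted p = 1.84e-05), Pde8a, a phosphodiesterase of cyclic AMP, 6.80-fold (its other probe set changed by −0.12 log2 units) and Snai1 5.92-fold. Anxa8 rose by 2.60, Timp4 by 2.27, Nr4a2, an orphan nuclear receptor, by 2.25 and Rdh10 by 2.23 (SE 0.18, 0.16, 0.19 and 0.11). Ccnd1, cyclin D1, rose by 1.00 (SE 0.10, adjusted p = 0.000185) and Casp6, an effector caspase, by 1.10 (SE 0.09, and 0.08 on its other probe set), while Vip changed by −1.36, Dusp1 by −1.27 and Id2 by −0.87. Set against the effect of 4-OHT in vector cells, the values of Vip and Id2 were −0.51 (adjusted p = 0.462) and −0.69 (adjusted p = 0.0646), and neither passed. In all 183 genes were higher and 166 lower, 41 and 8 of them by at least 2-fold, and 2087 had an unadjusted p under 0.05. The larger side depended on the scaling, with 145 higher and 195 lower after centring each array on its median and 181 and 187 after quantile normalization again. The total of 349 became 153 without uninduced replicate 2, 145 without induced replicate 1 and 129 without induced replicate 2.

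Some hypoxia and glycolysis genes also fell upon induction, with 1 of 27 higher, 10 lower and 16 not called (1 and 21 adjusted over the list alone) and a median of −0.39. Vegfa was the member that rose, by 0.74. Egln1 changed by −0.87 and Slc2a1 by −0.78 (SE 0.10 and 0.11). Camera gave adjusted p = 4.79e-18, or adjusted p = 0.211 with an estimated correlation. The list's difference from the 4-OHT effect in vector cells had a median of −0.51 (adjusted p = 8.06e-18, or adjusted p = 0.217 with an estimated correlation). The cell cycle list, called lower in the Runx3 line, was called higher here with a median of 0.13 and all 48 members short of the threshold on their own (adjusted p = 7.08e-05, or adjusted p = 0.255 with an estimated correlation). The stress list was called lower with a median of −0.17 (adjusted p = 9.76e-06) and the feedback list with 4 of 30 members lower (adjusted p = 0.00350), each with adjusted p = 0.255 with an estimated correlation.

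The effect of induction beyond that of 4-OHT in vector cells was tested as a difference of the 2 responses. In this test 110 genes passed, 89 higher and 21 lower. Its median SE was 0.165, against 0.117 for induction alone, so fewer genes can pass. Genes that did not pass are not thereby shown to respond to 4-OHT itself. The split was 69 and 28 after quantile normalization again and 66 and 23 after median centring. Snai1 led by 2.95 (SE 0.28, adjusted p = 0.000300), followed by Anxa8 at 2.94, Akr1c14 at 2.90 and Rdh10 at 2.90, to which the value of −0.67 in vector cells contributed. Pde8a at 2.75 (−0.12 on its other probe set), Nr4a2 at 2.38 and Junb at 2.10 also passed, as did Sdc1 at 1.25 and Nrp2, a receptor of semaphorins and VEGF, at 1.54. Dusp1 at −1.41 (SE 0.18, adjusted p = 0.00200), Mrgprf, an orphan receptor, at −1.31 and Egln1 at −1.08 were lower. Of the 148 genes shared by the constitutive lines, 20 of the higher and 9 of the lower were also among these 110 with the same sign. The total became 71 without induced replicate 2, 55 without vector replicate 1 and 66 without vector replicate 2.

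RUNX1-ER induction and the constitutive lines share no array, so their overlap is free of common controls. With mouse Runx1 the induction shared 88 calls of the same sign (39 higher, 49 lower, where independent lists would share 1.78 and 1.20) and 10 of opposite sign. It shared 180 with Runx2 (70 and 110, against 1.69 and 2.74, with 2 opposite) and 248 with Runx3 (109 and 139, against 7.27 and 8.96, with 6 opposite). Akr1c14, Anxa8, Snai1 and Col5a1 rose on induction and in the Runx3 line. Their changes of 0.09, 0.48, 0.00 and 0.00 in the Runx1 line did not pass. All 4 were higher in the Runx3 than in the Runx1 line (limma adjusted p = 4.22e-06, 2.46e-07, 1.03e-05 and 2.41e-07). They are named here for this pattern, which made that difference nearly certain. In the Runx2 line all 4 rose as well, by 3.57, 1.06, 1.165 and 0.90. Of the 349 genes called in the induction, 251 (71.9%) had the same sign in the Runx1 line, 319 (91.4%) in the Runx2 line and 315 (90.3%) in the Runx3 line. The correlation across the 8049 brighter genes was 0.266 with Runx1, 0.554 with Runx2, 0.616 with Runx3 and 0.406 with human RUNX1, and correction for replicate noise gave 0.368, 0.745, 0.765 and 0.528. The 88 shared with Runx1 became 49 without uninduced replicate 2, 44 and 40 without induced replicates 1 and 2, 45 and 52 without vector replicates 1 and 2, and 54 and 51 without Runx1 replicates 1 and 2.

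**Figure D4:**
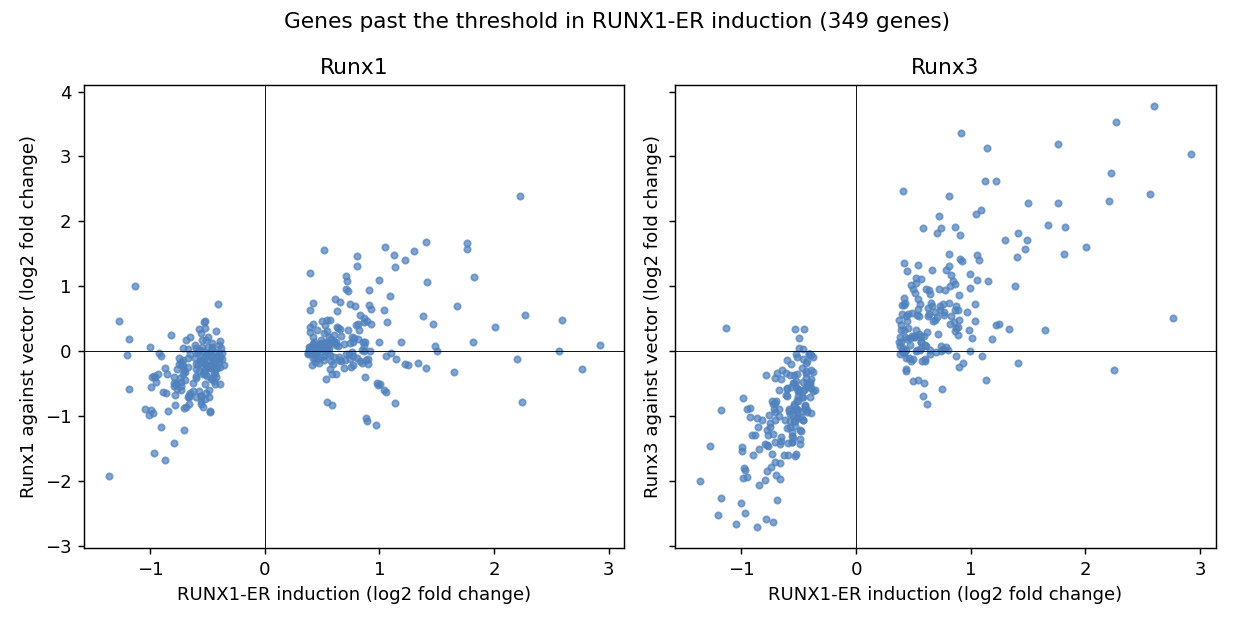
Log2 fold change in RUNX1-ER induction (horizontal axis) against that in the Runx1 line and in the Runx3 line (vertical axes) for the 349 genes called in the induction, each point a gene. In the Runx1 line 251 of the points had the same sign and in the Runx3 line 315. In the Runx2 line, which is not drawn, 319 of these genes did.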

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

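The tests with the shared vector arrays, with the growth of the cultures and with the spread of the Runx1 arrays were chosen only after the result was seen, as was leaving out vector arrays in the test of the correlations. The family members differed from each other when tested directly, in 273 genes between Runx2 and Runx1, 1186 between Runx3 and Runx1 and 684 between Runx3 and Runx2 (88 to 290, 641 to 802 and 251 to 448 with single arrays left out). The response to 4-OHT differed between RUNX1-ER cells and vector cells in 110 genes (55 to 127 with single arrays left out). Some genes passed the threshold in opposite directions against vector, and these were named after their values were seen. Between Runx1 and Runx2 they were 3, Prkg2 (0.63 against −0.54), Sned1 (−0.83 against 0.58) and Tcf7l1 (−0.49 against 0.66). Between Runx1 and Runx3 they were 12, among them Trib3 (1.03 against −1.10), the prostaglandin receptor gene Ptger4 (−1.07 against 0.87), the growth factor gene Hbegf (0.82 against −0.77), Snai2 (0.80 against −0.64) and Tmsb4x (0.60 against −0.97). Between Runx2 and Runx3 they were 3, Acsl3 (0.50 against −0.81), Mgp (−0.68 against 0.73) and Sned1 (0.58 against −0.50). Each of these pairs also differed line against line. Their selection made this nearly certain, since opposite changes against the same vector arrays add up in the direct difference. The fall of Mgp in the Runx2 line missed the threshold without vector replicate 1 (limma adjusted p = 0.175), Runx2 replicate 1 (0.0763) or Runx2 replicate 2 (0.0550), and most other genes of these 3 sets were not retested with arrays left out. Beyond the named genes, 11 probe sets without a gene symbol changed with the same sign in all 3 lines. No group had the 4 arrays needed to test for a single outlying array, and no comparison had 3 arrays per group for a count of other splits.

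Many genes of hypoxia and glycolysis were lower in the Runx2 and Runx3 lines. With an estimated correlation, camera called the list in neither line, nor upon RUNX1-ER induction. An effect of the shared vector arrays is argued against by RUNX1-ER induction, which uses none of them, where the highest median of the list over the 4 pairings of arrays was −0.23. A single array does not account for it, since the highest median in either line with any array of that line or the vector group left out was −0.40. A common change in growth would have moved cell cycle genes the same way in each setting. Their medians over the pairings ran from 0.0694 to 0.169 in RUNX1-ER induction, from −0.16 to −0.15 in the Runx3 line and from −0.02 to 0.01 in the Runx2 line. These small medians argue against a common direction, but not against slower growth in the Runx3 line by itself. Uninduced RUNX1-ER cells lay below vector cells, from −0.12 to −0.07, so the rise on induction began from a lower level. The fall was not general, since the medians over the pairings ran only from −0.13 to −0.03 in the mouse Runx1 line and from −0.16 to −0.04 in the line with human RUNX1. That the list responds to Runx activity in some of these settings stays a hypothesis, found and examined on the same arrays. Culture density, oxygen and the level of each transgene were not tested and may also have differed between the lines.

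RUNX1-ER induction resembled the Runx3 line more than the mouse Runx1 line, with noise-corrected correlations of 0.765 and 0.368. With the Runx2 line it was 0.745, close to Runx3, so the likeness was not particular to Runx3. Greater noise in the smaller changes of the Runx1 line is argued against. The corrected correlations of Runx1 and Runx3 still differed by 0.327 or more with any array of their groups, RUNX1-ER or vector cells left out. The hypoxia and glycolysis genes do not account for it either, as the difference was 0.399 without them. A candidate explanation is a difference between a pulse of human RUNX1 activity and stable mouse Runx1, but the stable line with human RUNX1, of 1 array, lay between them at 0.528, and species, duration and level were not varied one at a time.

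The Runx3 line changed more genes than the Runx1 line. The SD of the Runx1 replicate difference was 0.963 times that of Runx3, but this ratio does not test wider Runx1 spread as a cause. The fit pooled the spread over all groups, with a median SE of 0.117 in both comparisons. Wider spread in the Runx1 arrays would therefore not lower the Runx1 count alone. Nor does 1 array carry the difference, since the lowest ratio of the Runx3 count to the Runx1 count was 3.41, without Runx3 replicate 2. The level of each transgene was not compared and may differ, so the ratio is not shown to be a property of the proteins.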

How the results depend on the processing

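The alternatives that added quantile normalization, median centring and left-out replicates to the gene lists were chosen after seeing the data. No named gene and no list call reversed its direction under any alternative, but the larger side of some splits into higher and lower genes did. Of the values for named genes, 14199 stayed past the threshold and 2519 kept their direction but missed it, and of those for list calls 452 and 150 did. Of 1070 pairs of a named gene and a comparison, 663 stayed past the threshold with every array left out in turn. Quantile normalization, median centring and the mean of probe sets kept every count of genes within 1.5 times, and no scaling moved the median of all genes by more than 0.057. The array medians lay near the lower end of the scale, so this shift says little about brighter genes. The 75th percentile of the probe sets ran from 5.48 on the human RUNX1 array to 5.71 on induced replicate 1. The replicate numbers did not pair the arrays (correlations of deviations from −0.158 to 0.254 over 21 pairs of groups, 5 of them over 0.1), and with the number as a replicate block the counts were 311, 448 and 1668 for Runx1, Runx2 and Runx3 and 306 for RUNX1-ER induction. The block moved none of the counts of genes by over 1.5 times. For the counts that did move by more under other alternatives, the cause was not tested apart from what their construction shows. With an intensity trend and robust variance, Runx1 gave 552 genes, Runx2 770, the average of the lines 1310, RUNX1-ER induction 641, induction beyond 4-OHT 331, uninduced RUNX1-ER 88, Runx2 against Runx1 477, the genes common to the lines 251 and the overlap of RUNX1-ER with Runx1 154. With only genes of a group mean of at least 6, which leaves fewer genes to adjust over, they were 528 for Runx1, 716 for Runx2, 601 for RUNX1-ER induction, 289 for induction beyond 4-OHT, 63 for uninduced RUNX1-ER, 432 for Runx2 against Runx1, 243 for the common genes and 152 for the overlap. The added demand of 1 log2 unit left 71 genes for Runx1, 85 for Runx2, 254 for Runx3, 97 for the average, 198 for human RUNX1, 49 for RUNX1-ER induction, 61 beyond 4-OHT, 3 for uninduced RUNX1-ER, 39, 145 and 64 for Runx2 against Runx1, Runx3 against Runx1 and Runx3 against Runx2, 29 common genes and an overlap of 12. Fitted on only the groups compared, and so with fewer arrays, Runx1 gave 194, Runx2 161, RUNX1-ER induction 93, the direct comparisons 25, 709 and 86, the common genes 67 and the overlap 26, while human RUNX1 and uninduced RUNX1-ER gave 0 in limma (1447 at an unadjusted p under 0.05 for the latter in the fit of all groups). Against the vector arrays with 4-OHT, Runx1 gave 511 and uninduced RUNX1-ER 43, and against all 4 vector arrays Runx1 gave 531, the average 1621 and the common genes 230. Of the 309 genes of Runx1, 262 were also called against the 4-OHT vector arrays, as were 359 of the 468 of Runx2 and 1384 of the 1705 of Runx3. The split of higher and lower genes against those arrays was 354 and 157 for Runx1, 278 and 295 for Runx2, 1173 and 876 for Runx3, 753 and 532 for the average, 464 and 610 for human RUNX1 and 119 and 96 for the common genes, and against all 4 it was 1211 and 1130 for Runx3 and 857 and 764 for the average. Quantile normalization gave 566 higher and 484 lower genes for human RUNX1 and 181 and 187 for RUNX1-ER induction, and median centring gave 145 and 195 for the latter. For uninduced RUNX1-ER, array weights gave 16 genes and all probe sets 4. Of 63 list calls, 4 held with an estimated correlation. With each replicate left out in turn, the lowest and highest counts were 143 and 176 for Runx1, 207 and 482 for Runx2, 936 and 1206 for Runx3, 371 and 860 for the average, 524 and 781 for human RUNX1, 129 and 305 for RUNX1-ER induction, 0 and 4 for 4-OHT in vector cells, 55 and 127 beyond 4-OHT, 0 and 4 for uninduced RUNX1-ER, 88 and 290, 641 and 802, and 251 and 448 for the direct comparisons, 69 and 137 for the common genes, 40 and 67 for the overlap and 56 and 65 for list calls. A left-out replicate leaves 1 array in its group, whose spread is then taken from the others. In the self-test of Runx1 against vector, changes of 0.5 log2 units were recovered in 47.8% of cases, so small changes can be missed. The share was not measured for the other comparisons, which differ in how many genes changed and in their SE.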

Other observations

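These genes come from lists fixed in advance and follow the rule for named genes, and no test was chosen after the result was seen. Guidance genes changed one by one rather than as a list. Sema5a, a semaphorin, rose by 1.21 (SE 0.16, limma adjusted p = 0.00136) and Unc5b, a netrin receptor, by 1.18 (SE 0.15, adjusted p = 0.00102) in the Runx1 line, while no other probe set of either passed (−0.01 to 0.25 for 3 of Sema5a, 0.28 for 1 of Unc5b), and Sema5a changed by −0.03 in the Runx3 line (adjusted p = 0.962). Tested directly, Sema5a was lower in the Runx3 than in the Runx1 line by −1.24 (adjusted p = 0.000432). Sema3a, a repellent semaphorin, changed by −0.70 and −1.29 in the Runx2 and Runx3 lines. Efna5, an ephrin, changed by −0.59, −0.84 and −1.29 in the Runx1, Runx2 and Runx3 lines (0.10, 0.11 and 0.03 on its other probe set). Nrp2, a receptor that semaphorins and VEGF share, rose by 0.81 and 1.58 in the Runx2 and Runx3 lines and by 1.47 upon induction of RUNX1-ER. Of 44 guidance genes, 3 rose and 3 fell in the Runx1 line, 3 and 4 in the Runx2 line and 3 and 6 in the Runx3 line.

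Of 25 matrix proteases and inhibitors 2 rose and 3 fell in the Runx1 line, 2 and 3 in the Runx2 line and 5 and 6 in the Runx3 line, and the list was called in no comparison (lowest camera adjusted p = 0.265). Mmp2, gelatinase A, rose by 0.79, 0.64 and 0.59 (SE 0.09) in the Runx1, Runx2 and Runx3 lines. Timp3, an inhibitor bound to the matrix, changed by −0.64 and −0.80 (SE 0.09) in the Runx1 and Runx2 lines. It fell in the Runx3 line as well (limma adjusted p = 1.04e-05). Timp2 changed by −0.35, −0.52 and −0.94 in the Runx1, Runx2 and Runx3 lines. Timp4 had risen in the Runx3 line. Adamts4, an aggrecanase, rose by 0.69, 0.81 and 1.94 (SE 0.14) in the Runx1, Runx2 and Runx3 lines. It also rose by 1.68 upon induction of RUNX1-ER. In the same order, its other probe set changed by 0.11, 0.29, 0.47 and 0.57 and did not pass. Against a split between proteases and inhibitors, the proteases Adamts5 and Plat changed by −0.76 and −0.70 in the Runx3 line (0.18 on the other probe set of Plat, which did not pass), while the inhibitor Timp1 rose by 0.46. Among BMP-responsive genes, Id1 changed by −1.02 and −0.79 in the Runx1 and Runx2 lines and by 0.37 in the Runx3 line (adjusted p = 0.0845), and was higher in the Runx3 than in the Runx1 line by 1.39 (adjusted p = 1.60e-05). It rose by 0.89 (SE 0.12, limma adjusted p = 0.00171) upon induction of RUNX1-ER. Uninduced cells of that line had less of it than vector cells, a call that ended without uninduced replicate 2 or vector replicate 1. Smad6, an inhibitor of BMP signalling, rose by 1.65 (SE 0.14) upon induction. Other members of the TGF-β and BMP list went the other way, with Id2 at −0.87 and Id3 at −0.71.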
